A study of Mus musculus with 2 samples.

How the data were processed

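Midbrain tissue of mouse embryos at day 12.5 was used for H3K4me2 ChIP-seq in 2 replicates of 1 group, taken from the labels, which number them as biological replicates and give pools of 120 and 88 embryos. The labels give a fragment size range of 300 to 500 bp and the build mm10. Per the deposited text files, each replicate's peak list was made from its filtered alignments with a control alignment, the pooled list from the alignments of both replicates with both controls, and the replicated list from the replicate lists and the pooled list. The aligner, the peak caller, their versions and the thresholds are not given in the sources used here. The fold of a peak is a ratio of ChIP over control in the signal column of the narrowPeak format, as the authors deposited it, and its exact scaling is not given in the sources used here. The deposited lists also hold the −log10 p and −log10 q of each peak. The lowest −log10 p was 2.01 in replicate 1, 2.07 in replicate 2 and 2.00 in the pooled list. The narrowest peaks were 170, 185 and 180 bp. A weak peak just short of the caller's limit in one replicate is absent from its list, so overlap depends on where each list ends. No read counts or library sizes were used, so depth is unknown and no comparison of signal between replicates rests on it. Alignments and control libraries were not used here.

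Peak lists were read as deposited, with 0 columns of unmapped samples. The genome was GRCm38, the assembly behind mm10: the highest peak end on each of chromosomes 1 to 19, X and Y lay within that chromosome's length. Genes came from GENCODE vM21. Protein-coding genes on these chromosomes were kept once per symbol (27 second copies left out), which gave 21911 genes and 54408 TSSs of protein-coding transcripts. For 85 genes without such a transcript all TSSs were taken. A gene was marked if a peak overlapped the 1 kb either side of any of its TSSs by 1 bp. Its fold was the highest among such peaks, so the summit of a wide peak may lie outside the window, and neighbouring genes may share a peak. Peaks were classed in the order TSS window, exon, intron, intergenic. The TSS domain joined replicated peaks over gaps of up to 1 kb. Distal peaks lay more than 5 kb from every protein-coding TSS and were given to the gene with the nearest TSS within 500 kb, which need not be the gene they act on. Coordinates are 1-based.

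The tests, the 21 gene lists, the rule for named genes and most alternatives were fixed in advance. The lists are midbrain and isthmus patterning, floor plate and dopaminergic lineage, midbrain GABAergic and glutamatergic lineages, neural progenitors, young neurons, mature synapse and neuron subtypes, telencephalon, Hox clusters, glia, endothelium and pericytes, microglia and myeloid cells, erythroid cells, meninges and mesenchyme, neural crest and pigment cells, cardiac and skeletal muscle, liver, germ line, housekeeping, cell cycle, olfactory and vomeronasal receptors, and keratins with keratin-associated proteins. Of the symbols named one by one on 19 lists, 0 were missing from the annotation, and the other 2 lists were taken by symbol pattern. No list shared a gene with another (0 genes). The genes named are, per list, the 3 with the highest mean TSS fold and those lacking or having a replicated TSS peak where these number 5 or fewer, then the 10 widest TSS domains, the 10 genes with the most distal peaks, the 10 highest TSS folds, and per replicate the 5 highest-fold genes marked in that replicate alone. The domain and distal peaks of some of these genes are given as well. Genes named besides these in the closing section were chosen after their values were seen.

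TSS shares of lists were compared with all other protein-coding genes by Fisher's exact test. Median domain widths, for lists with at least 5 marked genes, and mean numbers of distal peaks were compared by permutation tests with 100000 resamples of random gene sets. Motif shares in distal peaks and in windows 10 kb away that hold no peak of any list were compared by McNemar's exact test. All tests were two-sided and adjusted by Benjamini-Hochberg, over lists or over 8 motifs, with a threshold of 0.05. They set genes or peaks against each other within these libraries, and genes and peaks are not independent replicates. Replicate overlap, correlations and genomic classes had no test, since 2 replicates of 1 group allow none between conditions. The p of the receptor family in Fisher's test lay below what the software can represent and is not printed.

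Alternatives were a −log10 q of at least 2, either replicate's own list or the pooled list in place of the replicated list, other overlap rules and equal or smaller peak numbers, TSS windows of 500 bp and 2 kb, joining gaps of 0 bp and 3 kb, distal peaks from 2 kb, counts per 100 kb of the DNA nearest to a gene's TSSs, and windows 50 kb away. Counting each shared domain once and windows of like GC content, within 2 points and 10 to 50 kb away, were added after the data were seen. The calculations were tested on simulated data. Interval functions differed from base-by-base counting and from bedtools in 0 of 9005 comparisons. Among 400 random lists of 20 simulated genes, p was under 0.05 in 2.00% for the TSS share, 4.25% for domain width and 5.00% for distal peaks. Among 200 seeded lists of 20 genes it was under 0.05 in 99.5% with a TSS share raised to 98%, in 87.5% with domain width doubled and in 99.0% with distal peaks raised 4 to 5 times. These simulated genes were drawn independently and shared no peaks, whereas neighbouring genes here may, so these rates need not hold for the gene lists. Among 200 lists of 60 simulated genes, 1.5% lay below the range of matched sets when the matched property was the whole cause and 100% with a further loss. Among 100 sets of 500 simulated sequences the motif test gave p under 0.05 in 5% with no word implanted and in 98% with a word implanted in 5%. Both arms of that simulation had the same base composition. Peaks and windows differed in GC and CpG content, so these rates need not hold for them. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1.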

Results

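H3K4me2, the dimethylated form of lysine 4 of histone H3, marks promoters and enhancers in accessible chromatin. It was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in midbrain tissue of mouse embryos at embryonic day 12.5. The series holds 1 group with 2 replicates, which were pools of the midbrains of 120 and 88 embryos of both sexes and of strain B6NCrl. It compares no conditions, so the design implies a comparison of the replicates and a description of where in the genome, and at which genes, the mark lay. The authors deposited 4 peak lists on mm10: one per replicate, one from both replicates pooled, and a list of replicated peaks. Replicate 1 had 49995 peaks, replicate 2 had 48027, the pooled list 49989 and the replicated list 37202. Read counts are not in these lists, so sequencing depth is unknown and no interval that needs it is given. The fold of a peak is the authors' own value, ChIP over control, and is used here to describe and rank peaks within a list. Where a fold, width or number is given as mean ± SD, it is over the replicates' own lists, n = 2, and a value of the pooled or replicated list has no SD.

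Whether the replicates gave the same peaks was compared first. At Otx2, which encodes a transcription factor that specifies the midbrain and forebrain, replicate 1 had 1 peak from 48654504 to 48675632 on chromosome 14 with a fold of 38.4, and replicate 2 had 1 from 48654206 to 48675986 with a fold of 34.4. A peak 3′ of the gene, from 48651490 to 48652525 in replicate 1, had a fold of 7.10 there and 7.14 in replicate 2. A cluster upstream of the gene led by a peak from 48709228 to 48711073 in replicate 1 was also called in both, with folds of 14.8 and 18.4 for that peak. A peak of 2.87-fold at 48643212 was in the list of replicate 1 and not in that of replicate 2, and a peak of 3.30-fold at 48616364 was in the list of replicate 2 and not in that of replicate 1, and the replicated list kept it, from 48616378 to 48616769 with a pooled fold of 2.79.

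**Figure D1:**
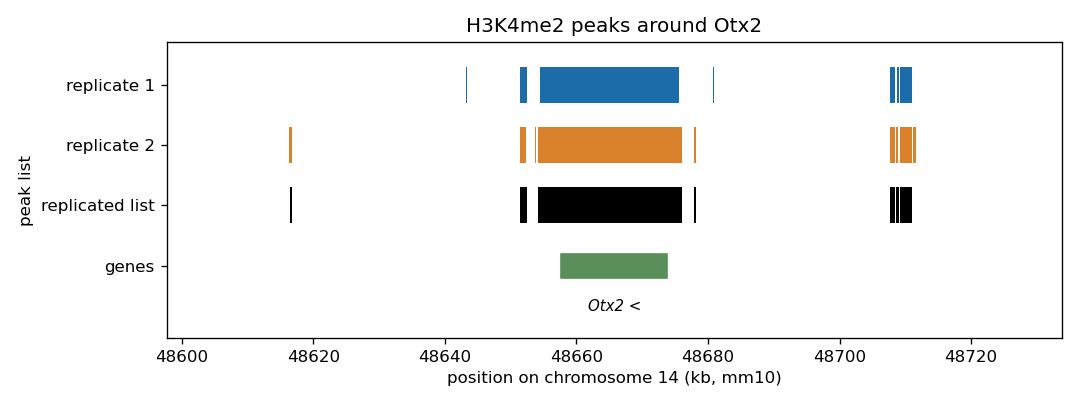
Peaks of H3K4me2 along chromosome 14 (horizontal axis, position in kb, mm10) around Otx2, which lies from 48657677 to 48673819 on the minus strand. Each bar is a called peak of replicate 1, replicate 2 or the replicated list, the green bar is the gene, and a single peak of more than 20 kb spans it in both replicates.

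Over the genome, 71.5% of the peaks of replicate 1 had at least 50% of their length covered by peaks of replicate 2, and 73.5% of the peaks of replicate 2 were so covered by replicate 1. When the other replicate's peaks were shifted along each chromosome 100 times, the median was 1.91% and 1.89%, and the highest value 2.22% and 2.17%. The base-pair Jaccard index was 0.775 on the assembled chromosomes, against a median of 0.0103 after shifting. The shared share was higher at higher fold. It was 24.7% and 27.5% for peaks under 3-fold in replicates 1 and 2, 50.8% and 54.2% from 3 to 5, 95.8% and 96.3% from 5 to 10, and 100% for the 13559 and 12942 peaks of 20-fold or more. Peaks without a counterpart had a median fold of 3.14 and 3.11 and a median width of 223 and 235 bp, against 12.5 and 12.1 and 987 and 1009 bp for shared peaks. With the 20000 strongest peaks of each replicate, ranked by −log10 p and not by fold, the shares were 97.2% and 96.3%. Across the 34206 pooled peaks that overlapped a peak of both replicates, the folds of the replicates correlated with Pearson r = 0.927 and Spearman rho = 0.926, and 97.8% of these peaks differed by less than 2-fold. These correlations are across peaks, which are not independent replicates.

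**Figure D2:**
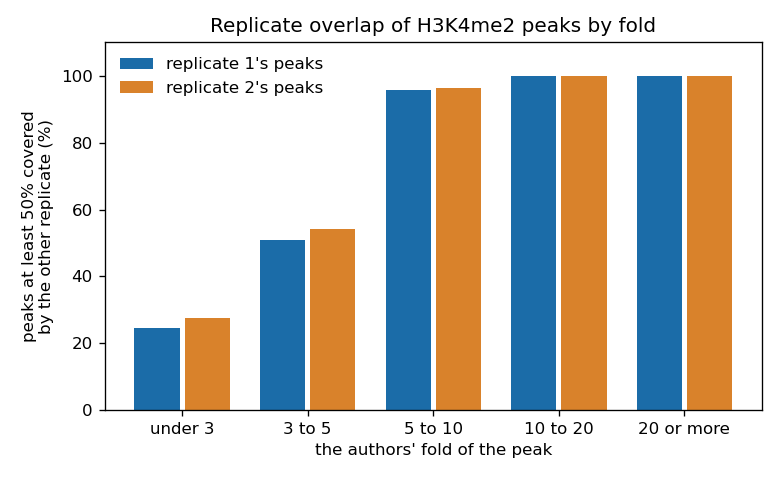
Percent of each replicate's H3K4me2 peaks with at least 50% of their length covered by the other replicate's peaks (vertical axis), by the authors' fold of the peak (horizontal axis). Each bar is 1 replicate's list; the share goes from 24.7% and 27.5% under 3-fold to 100% at 20-fold or more.

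The replicated list kept 74.4% of the pooled peaks, with the pooled coordinates and folds. Pooled peaks in it had a median fold of 10.9 and a median width of 1044 bp, and the 12787 left out had 2.63 and 225 bp. Of pooled peaks under 3-fold 19.6% were in the list, of those from 3 to 5-fold 83.2%, and of those of 10-fold or more 100%. A rule of at least 50% overlap, of either peak, with a peak in both replicates gave 33975 pooled peaks, each of them in the authors' list. The other 3227 peaks of that list, with a median fold of 3.12, met this rule in 1 replicate (3087) or in neither (140).

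H3K4me2 lay both at transcription start sites (TSSs) of protein-coding genes and far from them. Some of the peaks called distal here lay at TSSs of non-coding genes, which were not set apart. In a count chosen after the data had been seen, 1106 long non-coding RNA genes had a replicated peak at such a distant TSS. Their median pooled fold was 11.1. Of the 37189 replicated peaks on the assembled chromosomes, 16359 (44.0%) lay within 1 kb of a TSS of a protein-coding gene, 7.57% over other exons, 20.6% in introns and 27.8% between genes. Peaks at TSSs had a median fold of 29.9 and a median width of 2005 bp, and the 16383 distal peaks, more than 5 kb from every protein-coding TSS, had 4.91 and 661 bp. The TSS windows make up 2.44% of the genome and held 47.2% of the bases covered by replicated peaks, a 19.3-fold enrichment. In the replicates' own lists 36.9% and 37.6% of peaks lay at TSSs, 18425 and 18076 peaks against 23076 and 22119 distal ones, and the pooled list had 17357 against 24637.

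Of 21911 protein-coding genes, 14551 (66.4%) had a replicated peak within 1 kb of a TSS. The replicates' own lists gave 66.7% ± 0.0904 (SD, n = 2). Both replicates marked 14497 genes, and the fold at the TSS correlated across those genes with Spearman rho = 0.757, the width of the TSS domain with 0.934, and across all genes the number of distal peaks with 0.874. A TSS domain is the widest run of replicated peaks, joined over gaps of up to 1 kb, at a gene's TSSs. Its median was 2557 bp, and 160 genes had one of more than 10 kb.

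Genes of midbrain patterning, neural progenitors, young neurons, the GABAergic and glutamatergic lineages and the telencephalon carried the mark at their TSSs more often than other genes. The 18 genes of midbrain and isthmus patterning all had a replicated TSS peak, as did 21 of 21 genes of neural progenitors and 25 of 25 of young neurons, against 66.4% of other protein-coding genes in each case. Midbrain GABAergic and glutamatergic lineages had 24 of 25, and telencephalon 21 of 22. Among patterning genes the folds at the TSS were highest at Otx2, 36.4 ± 2.84, at Fgf18, a growth factor of the isthmus, 35.1 ± 0.638, and at Meis2, a homeodomain factor of the dorsal midbrain, 30.4 ± 2.50. In neural progenitors they were highest at the Notch effector Hes1, 42.2 ± 4.21, at Sox9, 40.1 ± 1.98, and at the RNA-binding protein gene Msi1, 36.5 ± 6.03. In young neurons they were highest at Scrt1, a zinc finger repressor of neurons, 41.0 ± 7.47, at Rbfox3, which encodes the NeuN antigen, 40.4 ± 5.33, and at the synaptotagmin gene Syt1, 39.9 ± 1.42. In the GABAergic and glutamatergic list they were highest at Isl1, 35.3 ± 5.68, Barhl2, 31.4 ± 5.72, and Tcf7l2, 31.3 ± 0.138, all transcription factors, and Phox2b, a determinant of motor and visceral neurons, had no TSS peak in either replicate. In the telencephalon list they were highest at Dlx2, 43.6 ± 3.69, Satb2, 41.9 ± 2.47, and Emx1, 38.0 ± 0.111, and Neurod6 had no TSS peak. By Fisher's exact test, two-sided and adjusted over the 21 lists, p was 0.00184 for patterning, 6.93e-04 for progenitors, 1.60e-04 for young neurons, 0.00198 for the GABAergic and glutamatergic lineages and 0.00427 for telencephalon. Against genes matched on the CpG content of the TSS, a comparison chosen after the data were seen, young neurons passed as higher (100% against a median of 72%). For the other 4 lists the medians of matched sets were 94.4% to 96% and their ranges reached 100%, so none of these 4 could have passed as higher.

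The housekeeping list had 26 of 26 and the cell cycle list 16 of 16 (Fisher's exact test, adjusted p = 1.09e-04 and 0.00427). Sets of genes matched on CpG content had a median of 100% for both, so a higher share was not possible. The highest folds were 43.3 ± 0.548 at the ubiquitin gene Ubc, 42.2 ± 1.43 at the elongation factor gene Eef2 and 39.5 ± 4.87 at the ribosomal gene Rps18, and among cell cycle genes 38.4 ± 2.20 at Ccnd1, 37.8 ± 2.75 at Ccnb1 and 37.3 ± 0.665 at Aurkb.

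In the floor plate and dopaminergic list, 15 of 18 genes had a replicated TSS peak, which did not pass the test against other genes (adjusted p = 0.294, Fisher's exact test). The highest folds were at the receptor gene Ret, 39.7 ± 8.48, at the axon guidance gene Ntn1, 36.9 ± 0.0100, and at Wnt5a, 34.7 ± 0.0989. The 3 genes without one were Th and Ddc, whose products make dopamine, and the aldehyde dehydrogenase gene Aldh1a1. Th had a TSS peak of 2.88-fold in replicate 1 and none in replicate 2, and Ddc one of 3.15-fold in replicate 2 and none in replicate 1. The mature synapse list had 17 of 19 (Fisher's exact test, adjusted p = 0.0723). It was led by the potassium channel genes Kcna1, 47.0 ± 3.34, and Kcnc1, 34.6 ± 3.16, and the neurotrophin gene Bdnf, 37.2 ± 3.95. Vip and Gabra6 had no TSS peak. With TSS windows of 500 bp the mature synapse list passed the test (89.5% marked).

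Genes of blood, liver and germ cells, and the large receptor and keratin families, had TSS peaks less often than other genes. The microglia and myeloid list had 2 of 16 (Fisher's exact test, adjusted p = 5.50e-05), the transcription factor gene Runx1 with a fold of 42.9 ± 2.73 and the purinergic receptor gene P2ry12 with 4.06 ± 0.173. The erythroid list had 4 of 13 (Fisher's exact test, adjusted p = 0.0229), Klf1 at 33.0 ± 2.82, Nfe2 at 24.5 ± 3.96, Gypa at 23.5 ± 3.82 and Epor at 19.2 ± 5.19. Without replicate 2, on replicate 1's own list, 38.5% of the erythroid genes were marked and the list did not pass, as in the pooled list, with the same share. The liver list had 3 of 19 (Fisher's exact test, adjusted p = 4.25e-05), Cebpa at 39.9 ± 6.06, Foxa3 at 30.9 ± 10.6 and Apob at 5.77 ± 0.995, and the germ line list 1 of 19 (adjusted p = 2.65e-07), Dazl at 17.2 ± 1.35. Of 1418 olfactory and vomeronasal receptor genes 4 were marked (0.282%), namely Olfr94 at 36.6 ± 5.22, Vmn1r4 at 15.8 ± 3.06, Olfr658 at 13.6 ± 1.5 and Olfr1033 at 7.10 ± 0.432, against 71.0% of other genes. The TSS domains of Foxa3 and Vmn1r4 were each shared with another gene. Of 105 keratin and keratin-associated genes 8 were marked (Fisher's exact test, adjusted p = 8.65e-36), led by Krt87 at 22.8 ± 1.80, Krt10 at 21.8 ± 9.50 and Krt8 at 14.7 ± 1.62. Against the sets matched on CpG content, germ line, receptors and keratins passed as lower, and the myeloid (12.5% against a median of 25%), liver (15.8% against 26.3%) and erythroid lists (30.8% against 23.1%) did not pass. With TSS windows of 2 kb the germ line share was 15.8% and the liver share 26.3%, and with 500 bp the liver share was 10.5%, all passing as lower than other genes.

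The 8 lists that did not pass the test include the floor plate and mature synapse lists and those of several other cell types that a midbrain dissection could hold. The Hox clusters, which pattern the hindbrain and spinal cord, had 23 of 39 genes marked (adjusted p = 0.405, Fisher's exact test), though below the 92.3% of sets matched on CpG content, led by Hoxa1, 40.4 ± 0.508, Hoxd1, 26.9 ± 7.05, and Hoxa7, 25.1 ± 4.00. Their marked members had a median fold of 6.54. Cardiac and skeletal muscle had 10 of 18 (exact test, adjusted p = 0.405), led by Hand2, 22.7 ± 0.489, Des, 15.5 ± 1.08, and Tnni3, 11.99 ± 0.408, and with windows of 500 bp 33.3% were marked and the list passed as lower. Glia had 10 of 15 (exact test, adjusted p = 1.00), led by the glutamate transporter gene Slc1a2, 34.4 ± 0.0457, the myelin gene Mbp, 31.8 ± 11.6, and Pdgfra, 29.1 ± 2.47, and S100b, Gfap, Mog, Mag and Plp1 had no TSS peak. Endothelium and pericytes had 13 of 18 (exact test, adjusted p = 0.888), led by Kdr, 44.5 ± 2.51, Erg, 40.7 ± 2.52, and Kcnj8, 38.5 ± 0.257, while Pecam1, Emcn, Tek, Tie1 and Cdh5 had no replicated TSS peak. Meninges and mesenchyme had 10 of 12 (exact test, adjusted p = 0.419), led by Prrx1, 33.9 ± 4.90, Foxc1, 33.2 ± 7.31, and Col1a2, 29.1 ± 1.20, and Col3a1 and Lum had no TSS peak. Neural crest and pigment cells had 7 of 10 (exact test, adjusted p = 1.00), led by Mitf, 50.5 ± 4.88, Kit, 44.2 ± 3.88, and Ednrb, 33.5 ± 1.28, and the pigment genes Mlana, Tyrp1 and Tyr had no TSS peak. Genes are not independent replicates, and these p-values describe these 2 libraries.

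**Figure D3:**
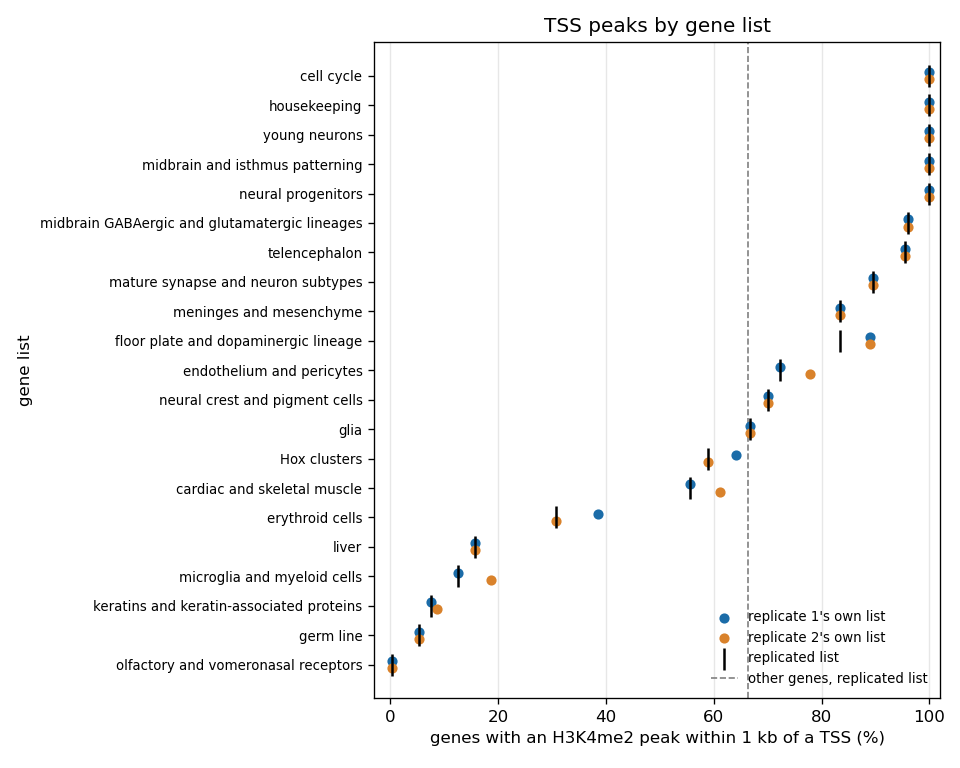
Percent of the genes of each list (vertical axis) with an H3K4me2 peak within 1 kb of a TSS (horizontal axis). Points are the replicates' own lists, the black mark is the replicated list and the dashed line the other genes, for which it was 66.4%; the lists run from 0.282% for olfactory and vomeronasal receptors to 100%.

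TSS domains were wide at genes of midbrain development, neural progenitors and young neurons. The median domain was 10362 bp in the GABAergic and glutamatergic list, 8455 bp in midbrain and isthmus patterning, 7859 bp in neural progenitors, 6051 bp in young neurons, 4546 bp in telencephalon, 4144 bp in the floor plate and dopaminergic list and 3924 bp in housekeeping, against 2555 to 2557 bp in the other marked genes. In the replicates' own lists these medians were 10409 ± 263, 8284 ± 1466, 8278 ± 279, 5790 ± 438, 4105 ± 990, 3163 ± 800 and 3653 ± 101 bp. The widest domain of any gene was at Nr2f1, a nuclear receptor gene of the developing brain, with 42664 bp (41723 ± 660), from 78169687 to 78212350 on chromosome 13, followed by Sox2, the transcription factor gene of neural stem cells, with 32120 bp (26530 ± 7135), from 34637254 to 34669373 on chromosome 3, Pou3f3 with 31634 bp (31584 ± 6.36), Nr2f2 with 30762 bp (31112 ± 1971) and Zfhx3 with 25619 bp (25463 ± 59.4). Tcf7l2, an effector of Wnt signalling, had 24912 bp, Meis2 24436 bp, and Pax6 24195 bp. The neighbours Zic1 and Zic4 shared 1 domain of 24404 bp, which was 40884 bp without replicate 2, on replicate 1's own list, and 24380 bp in replicate 2. Otx2 had 21802 bp (21710 ± 822).

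Narrow domains were found in the Hox clusters, cardiac and skeletal muscle and keratins. Their marked genes also had low folds, with medians of 6.54, 10.7 and 13.8, against 32.5 at marked protein-coding genes. Whether the low folds account for the narrow domains was not tested. The median domain was 922 bp in the Hox clusters (770 ± 70.7 in the replicates' own lists), 996.5 bp in cardiac and skeletal muscle (994 ± 24.4) and 881.5 bp in keratins (788 ± 175). By a permutation test, two-sided with 100000 resamples and adjusted over the 16 lists with at least 5 marked genes, p was 4.57e-05 for patterning, the GABAergic and glutamatergic list, progenitors, young neurons, telencephalon, Hox and keratins, each at the smallest raw p these resamples can give, 2e-05. It was 8.00e-05 for cardiac and skeletal muscle, 9.96e-04 for housekeeping and 0.00458 for the floor plate list. The other 6 lists did not pass: mature synapse (2824 bp), cell cycle (3276.5 bp), meninges and mesenchyme (2608.5 bp), neural crest (2453 bp), endothelium (1875 bp) and glia (1870.5 bp). Without replicate 1 the floor plate median was 2597 bp and did not pass, and with replicate 1 alone 2 more lists, erythroid cells and the olfactory and vomeronasal receptors, had enough marked genes to be tested and were narrower, which made 5. With no gap joined, the floor plate list (2184 bp, against 2272.5 bp in other genes), telencephalon (2879 bp) and housekeeping (2613.5 bp) did not pass, cell cycle (3085 bp) passed as wider, and the GABAergic and glutamatergic median was 4647 bp and still passed, while with gaps of up to 3 kb joined the medians were 16404 bp in patterning, 9526 bp in the floor plate list and 8196 bp in telencephalon, all passing as wider, and 4145.5 bp in glia, above the 2696 bp of other genes, which did not pass.

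**Figure D4:**
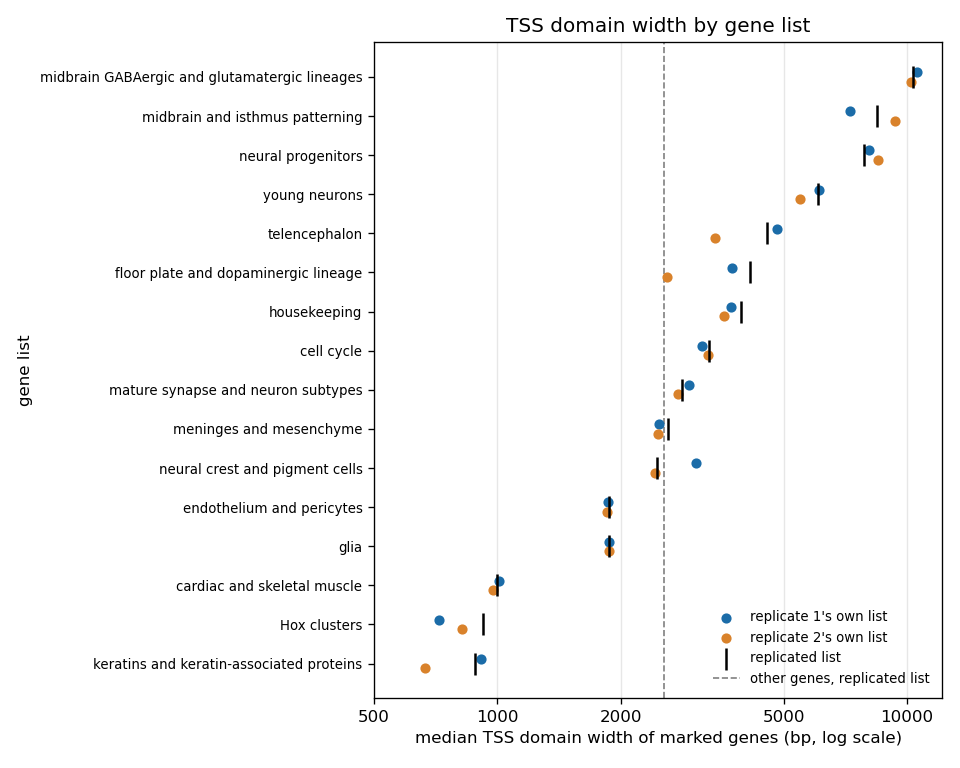
Median width of the TSS domain of marked genes in bp (horizontal axis, log scale) for the 16 lists tested (vertical axis). Points are the replicates' own lists, the black mark is the replicated list and the dashed line the other marked genes at 2557 bp; the replicated medians run from 881.5 bp for keratins to 10362 bp for the GABAergic and glutamatergic list.

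Distal peaks were more numerous at most of the lists with wide domains, though not at housekeeping genes. They were also more numerous at neural crest and pigment cell genes, whose domains did not pass as wider. A peak within or next to a wide domain counts as distal where it lies more than 5 kb from every protein-coding TSS. Domain width and distal peaks are thus not fully separate measures, and no count without such peaks was made. Genes of midbrain and isthmus patterning had a mean of 7.33 distal peaks, those of neural progenitors 6, of the GABAergic and glutamatergic lineages 4.52, of telencephalon 4.41, of neural crest and pigment cells 3.90, of young neurons 3.12 and of the floor plate and dopaminergic list 3.11, against 0.73 in other genes. In the replicates' own lists they were 10.7 ± 0.943, 8.95 ± 0.943, 7.16 ± 0.849, 5.80 ± 0.161, 4.55 ± 0.0707, 4.06 ± 0.481 and 4.06 ± 0.157. Otx2 had 19 distal peaks (23.0 ± 1.41), and Sox9, a gene of progenitors and glia, 21 (34.0 ± 7.07). The genes with the most were Zfhx3 with 43 (54 in each replicate), Zfp608 with 39 (58.0 ± 11.3), Gse1 with 36 (60.5 ± 6.36), the predicted genes Gm11146 with 32 (42 and 34) and Gm26897 with 27 (34.0 ± 1.41), and with 26 each Adgrl2 (32.5 ± 0.707), Efna5 (47.0 ± 5.66), Nr2f2 (37.0 ± 7.07), Sox2 (32.5 ± 0.707) and Ubash3b (32 in each replicate). Without replicate 2, on replicate 1's own list, Zfp608 had 66, Nr2f2 42 and Sox9 39, and the means were 11.4 in patterning, 9.62 in progenitors and 7.76 in the GABAergic and glutamatergic list, which had 6.84 in the pooled list. Gm11146 and Gm26897 had no TSS peak in either replicate.

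By the permutation test, two-sided with 100000 resamples and adjusted over 21 lists, p was 7.00e-05 for patterning, progenitors, the GABAergic and glutamatergic list and telencephalon, 7.80e-04 for young neurons, 0.00619 for the floor plate list and 0.0112 for neural crest. Distal peaks were fewer than in other genes in the olfactory and vomeronasal receptors (0.0409, adjusted p = 7.00e-05), the keratins (0.114, adjusted p = 7.00e-05) and the Hox clusters (0.179, adjusted p = 0.0242), by the same permutation test. The other 11 lists did not pass: glia (1.53), meninges (1.42), microglia and myeloid cells (1.38), cell cycle (1.25), cardiac and skeletal muscle (1.06), endothelium (0.833), mature synapse (0.632), housekeeping (0.462), liver (0.316), germ line (0.316) and erythroid cells (0.231). Without replicate 1, mature synapse had 1.05, above the 0.990 of other genes, germ line 0.526, housekeeping 0.692 and erythroid cells 0.385. Without replicate 2, glia had 2.40, housekeeping 0.846 and erythroid cells 0.385. The pooled list gave 2.53 in glia, 2.25 in meninges, 1.44 in endothelium, 1.16 in mature synapse, 0.846 in housekeeping, 0.474 in liver and 0.385 in erythroid cells. None of the values of these 11 lists without a replicate or in the pooled list passed. The number of distal peaks followed the length of the surrounding DNA nearest to a gene (Spearman rho = 0.480 across genes). Per 100 kb of that DNA, the floor plate list (1.26), neural crest (1.11), the Hox clusters (0.533) and the keratins (0.580) did not pass, and neither did the Hox clusters with distal peaks counted from 2 kb (0.308), where housekeeping had 0.923 and meninges 2.17.

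The highest folds at TSSs belonged to genes outside these lists. They were at the ubiquitin protease gene Usp43, 64.3 ± 1.86, the glycosyltransferase gene Galnt3, 59.7 ± 8.02, the immediate early gene Egr1, 58.9 ± 5.03, the adhesion receptor gene Adgrg6, 56.4 ± 0.721, and Lypd6b, 55.4 ± 1.87. Vgll4 followed with 55.1 ± 3.51, Cabp1 with 54.6 ± 3.04, Tbc1d1 with 54.5 ± 1.27, Ppargc1b with 54.3 ± 0.345 and Apoh with 54.2 ± 2.40. Among these 10, the narrowest domain was 1429 bp at Lypd6b and the widest 8278 bp at Vgll4, and Usp43 had 1891 bp. The domain of Apoh was shared with another gene.

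Few genes had a TSS peak in 1 replicate alone: 132 in replicate 1 and 104 in replicate 2, with a median fold of 3.14 and 3.08, against 29.1 and 27.8 for genes marked in both. The highest in replicate 1 were Gm28035 (42.3), Tchh (39.98), Tsks (24.2), Gsg1 (15.4) and Tmem150b (15.1), and in replicate 2 Bricd5 (45.1), Igflr1 (22.6), Gpr182 (7.54), 9030025P20Rik (6.30) and Gm26602 (6.30). In a comparison chosen after these values were seen, 9 of the 10 genes had in the other replicate a peak that overlapped theirs with its nearer edge 1019 to 1216 bp from a TSS, outside the 1 kb window. At Gm28035 that peak had a fold of 37.8, at Tchh 33.4 and at Bricd5 39.9. The exception was 9030025P20Rik, whose peak in replicate 2 lay 124 bp from a TSS and overlapped no peak of replicate 1. Gsg1 and Gm26602 had no replicated TSS peak. With 1 group of 2 replicates, a difference between them cannot be tested.

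Peaks were compared in sequence with nearby DNA. The median GC content was 53.3% in TSS peaks and 50.5% in distal peaks, against 44.4% and 44.9% in windows of the same length 10 kb away, and the CpG observed/expected ratio was 0.559 and 0.353 against 0.187 in both. Of 16054 distal peaks with such a window, 2.83% held the CTCF motif CCASYAGRKGGC against 0.536% of windows, 2.79% the RFX motif GTTGCYATGG against 0.660%, 44.0% the E-box CAGCTG against 29.2%, and 7.13% the POU motif ATGCAAAT against 4.91%. CTCF is the insulator protein, RFX factors act at genes of cilia, the E-box CAGCTG is bound by proneural factors, and POU factors include those of neural progenitors. By McNemar's exact test, two-sided and adjusted over 8 motifs, p was 2.07e-62 for CTCF, 8.87e-51 for RFX, 2.02e-187 for CAGCTG and 1.87e-17 for POU. The E-box CAGATG was rarer in peaks (44.6% against 45.9%, exact test, adjusted p = 0.0218), and without replicate 2 this did not pass (-0.777 percentage points). SOX ACAAWG (64.0% against 63.1%, adjusted p = 0.0652), homeodomain TAATTA (18.9% against 19.8%, adjusted p = 0.0542) and NFI TTGGCNNNNNGCCAA (0.112% against 0.0747%, adjusted p = 0.362) did not pass the exact test, though SOX ACAAWG passed as higher in either replicate's own list (by 1.28 and 1.66 percentage points in replicates 1 and 2). With windows 50 kb away SOX ACAAWG was as frequent in windows as in peaks (64.1% in both). TAATTA passed as lower at a −log10 q of at least 2 (-0.922 percentage points) and with windows 50 kb away (-0.908). Against windows of like GC content, an alternative chosen after the data were seen and tested by the same exact test, TAATTA was more frequent in peaks (21.1% against 13.0%, adjusted p = 8.33e-62), as was SOX ACAAWG (66.3% against 58.7%, adjusted p = 6.60e-35). For the 10681 distal peaks with such a window, CAGCTG (41.0% against 35.2%), POU (7.97% against 3.57%), RFX (3.07% against 0.627%) and CTCF (2.57% against 0.665%) passed as higher as well. CAGATG passed as lower (44.2% against 47.0%), and NFI did not pass (0.103% against 0.0843%). Without replicate 1 the difference was -0.557 percentage points for TAATTA and 0.0138 for NFI, and neither passed. Peaks are not independent replicates, so these p-values describe these libraries.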

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

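Both counts given next were chosen after the data had been seen. H3K4me2 also lay at genes outside the protein-coding set: 1106 of the 7622 long non-coding RNA genes with a TSS more than 5 kb from every protein-coding TSS (14.5%) had a replicated peak at such a TSS, and the replicates' own lists marked 1193 and 1148. Their median pooled fold was 11.1, against 32.5 at protein-coding genes, and among the highest were Lncpint with 52.1 ± 9.50, Snhg20 with 44.8 ± 2.98 and Mir155hg, the host gene of a microRNA, with 42.2 ± 3.21 (SD, n = 2). On 6 scaffolds outside the assembled chromosomes the replicated list held 13 peaks, with a median fold of 8.36 and a highest of 13.4, and the replicates' own lists held 15 and 16.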

How the results depend on the processing

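Counting each shared domain once and windows of like GC content were chosen only after the results were seen. Among the alternatives set before the data were examined, 415 values kept their side of the threshold or stayed within the spread, 26 without a test moved, calls were lost with the direction kept in 11 and gained in 7, and in 1, the floor plate domains with no gap joined, the call was lost and the value changed side; counting each shared domain once changed no call. The cause was not tested for any change unless stated. The peaks of replicates 1 and 2 that were shared made up 77.4% and 79.4% with any overlap and 61.2% and 63.7% with reciprocal overlap. At a −log10 q of at least 2 they made up 77.5% and 79.0%. With peaks ranked by −log10 p, they made up 73.6% and 72.8% with equal numbers and 97.2% and 96.3% for the strongest 20000. Spearman rho of the −log10 p was 0.950. The replicated share of pooled peaks was 68.0% by the recomputed rule and 80.0% at the stricter q. The TSS share of peaks was 36.9% to 37.6% when a replicate was left out, 34.7% in the pooled list, 42.4% at 500 bp and 48.1% at 2 kb, where narrower or wider windows by construction hold fewer or more peaks. At 500 bp mature synapse (89.5%) and cardiac and skeletal muscle (33.3%) passed. Erythroid cells went from 30.8% to 38.5% when a replicate was left out and had 38.5% in the pooled list, where the call was lost. The number of lists with narrower domains was 4 to 5 when a replicate was left out, because more lists then had enough marked genes to be tested. The floor plate domain median was 2597 to 3728.5 bp when a replicate was left out and 2184 bp, below other genes, with no gap joined, where telencephalon (2879 bp) and housekeeping (2613.5 bp) lost and cell cycle (3085 bp) gained the call. The floor plate median was 9526 bp with gaps of up to 3 kb joined and 5885 bp in the pooled list. Per 100 kb, 1 list had fewer distal peaks, and the calls of the floor plate list (1.26), Hox clusters (0.533), neural crest (1.11) and keratins (0.580) were lost. From 2 kb the Hox clusters had 0.308 and did not pass. Leaving out a replicate gave a GC content of 53.5% to 53.6% in TSS peaks and 50.4% to 50.6% in distal peaks, and a CpG ratio of 0.561 to 0.564 and 0.333 to 0.335. The excess of motifs in distal peaks, in percentage points, was -1.003 to -0.777 for CAGATG and 1.28 to 1.66 for SOX ACAAWG when a replicate was left out. For TAATTA it was -0.922 at the stricter q and -0.908 with windows 50 kb away, both passing as lower, and 8.10 with windows of like GC, where it passed as higher, and for SOX ACAAWG 7.65 with these and 0 with windows 50 kb away. For CAGATG it was -2.79 with windows of like GC. Read depth is unknown, so whether weak peaks of 1 replicate were missed in the other for want of reads could not be tested. No paired analysis was possible because there is 1 group.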

Other observations

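The 14 gene families, the matching of each list on CpG content, the chromosome summary, the windows of like GC content, the use of all the palindromes of CAGCTG beside the highest, and the separate tests of the germ line list and of the myeloid, erythroid and liver lists were chosen only after results had been seen, and so were the genes named here. Families of developmental regulators carried broad marks. Of 19 Sox factors 18 had a replicated TSS peak, with a median domain of 6721 bp and a mean of 7.42 distal peaks, led by Sox2 with 32120 bp, Sox21 with 14376 bp and Sox11 with 10283 bp. All 12 LIM homeodomain genes were marked (median domain 4545 bp), with 23710 bp at Lhx2, 22228 bp at Lhx1 and 18713 bp at Lhx9, and all 12 homeobox genes of a family set made of the Irx genes and Six3 with its paralogs (4590.5 bp), with 17061 bp at Six3 and 15901 bp at Irx5. Axon guidance genes had 64 of 67 marked and a median domain of 4670 bp, with 14239 bp and 26 distal peaks at the ephrin gene Efna5 (43 and 51 in the replicates' own lists). Forkhead genes had 38 of 44 and 3180.5 bp, with 16297 bp at Foxa1 (9356 bp without replicate 1) and 16004 bp at Foxb1. These 5 families had wider domains and more distal peaks than other genes by permutation tests, two-sided and adjusted over the families, with the forkhead domains at an adjusted p of 0.0336. Sox1, Sox2, Sox3, Sox9, Sox21, Lhx1, Lhx2, Lhx5, Six3, Foxa1 and Foxa2, among others, are also members of gene lists with wider domains. These tests thus count many of the same genes again and are not independent of the list results. Wnt, Fgf and Bmp ligands had 45 of 52 marked and more distal peaks (1.48, permutation test, adjusted p = 0.0321), while their domains of 2748 bp did not pass (adjusted p = 0.453). Distal peaks of the families were not counted per 100 kb of the DNA nearest to a gene. Among the lists, that count lost the calls of more distal peaks for floor plate and neural crest and kept those of the others.

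The domains of the other families tested did not pass as wider. Zinc finger genes named Zfp had 321 of 365 marked with a median domain of 2259 bp, narrower than the 2562 bp of other genes (permutation test, adjusted p = 5.72e-04). Ribosomal protein genes had 76 of 79 (2900.5 bp), potassium channels 77 of 92 (2448 bp) and glutamate and GABA receptor subunits 39 of 43 (2824 bp), each marked more often than other genes by Fisher's exact test and with domains that did not pass. Clustered protocadherins, adhesion proteins of neurons, had 18 of 56 marked (32.1%, Fisher's exact test, adjusted p = 4.23e-07) with a median domain of 841.5 bp, and the widest was 6030 bp at Pcdhgc3. Chemokines and interleukins had 17 of 65, cytochromes P450 15 of 80 and defensins 0 of 42, all 3 lower by the same exact test. On chromosome X 490 of 948 genes were marked (51.7%), with a mean of 0.310 distal peaks per gene. The autosomes had 67.6% and 0.759, and ranged from 55.1% and 0.436 on chromosome 7 to 81.0% and 1.20 on chromosome 12. These differences were not tested, and the chromosomes were not matched on the CpG content of their TSSs. The copy number of X in these pools of both sexes was not taken into account.

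TSS peaks followed the CpG content of the TSS. In 4 groups of equal size, from the lowest to the highest CpG observed/expected ratio, 4.62%, 63.4%, 98.1% and 99.6% were marked. Against 10000 sets of genes matched on that ratio, 4 of 21 lists were marked less often and 1 more often, each at the smallest p these permutation sets can give, 2e-04 (adjusted 8.40e-04). The Hox clusters had 59.0% against a median of 92.3% in matched sets, germ line 5.26% against 52.6%, keratins 7.62% against 25.7%, olfactory and vomeronasal receptors 0.282% against 6.91%, and young neurons 100% against 72%. For patterning, progenitors, the GABAergic and glutamatergic list, telencephalon, housekeeping and cell cycle the matched sets reached 100%, so this comparison could not show a higher share.

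The wide domains of patterning, GABAergic and glutamatergic, progenitor, young neuron and floor plate genes were weighed against 3 technical explanations. The median domain of the 103 marked genes of these 5 lists together was 7987 bp, where the floor plate list alone was not wider without replicate 1 (2597 bp). Sets of marked genes matched on CpG content had a median of 2485 bp (95% of sets from 2253 to 2771). Sets matched on the fold of the TSS peak had 2416 bp (2153 to 2699), and sets matched on the number of annotated TSSs 2543 bp (2266 to 2844). None of these, matched alone and as measured here, accounts for the width. The CpG ratio was taken within 500 bp of a TSS, so the length of CpG-rich DNA was not matched and stays open. Telencephalon (4546 bp) and housekeeping (3924 bp) genes also had wider domains than other genes. With 1 group, no biological explanation was tested.

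The low TSS share of the myeloid, erythroid, liver and germ line lists, 14.9% of 67 genes, lay below that of sets matched on CpG content, 32.8% (25.4 to 40.3), and on the number of TSSs, 64.2% (53.7 to 76.1). Taken apart, germ line had 5.26% against 52.6% (36.8 to 68.4), and the other 3 lists together 18.75% against 22.9% (14.6 to 33.3), within the range of matched sets. For myeloid, erythroid and liver genes low CpG content is thus a candidate explanation of the low share, and it does not account for that of germ line genes. With 1 group, no biological explanation was tested.

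The excess of CAGCTG in distal peaks, and that of TAATTA, which was seen only against windows of like GC content (18.9% against 19.8% in windows 10 kb away), were weighed against base composition, with windows of like GC content and other palindromes of the same bases. The odds for CAGCTG were 1.32 (95% interval 1.25 to 1.40). Of the 9 other palindromes CTGCAG had 1.34 and the remaining 8 had 0.661 to 0.981. By the rule set beforehand, odds within those of the other palindromes fit base composition, and CAGCTG met it. The remaining 8, weighed only after results were seen, were not more frequent in peaks, so whether base composition accounts for the excess stays open. For TAATTA the odds were 1.93 (1.79 to 2.09), above the highest of 7 others, 1.70 at ATTAAT. Its interval lay above the odds of all 7, which by the rule set beforehand speaks against base composition as the whole cause. The interval of ATTAAT, 1.56 to 1.84, overlaps that of TAATTA. ATTAAT holds the shorter words TAAT and ATTA, as TAATTA does, so this overlap cannot tell base composition from these words. The next highest, TTTAAA, had 1.60 (1.49 to 1.70). The CpG ratio also still differed, 0.338 in these peaks against 0.193 in their windows of like GC. Whether base composition accounts for all of the TAATTA excess thus stays open. No biological explanation was tested.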
